A study of Arabidopsis thaliana with 6 samples.

How the data were processed

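RNA of Arabidopsis thaliana leaves was measured on 6 Affymetrix microarrays, 3 of the wild-type accession Col-0 and 3 of pam48, a mutant whose second name in the labels is mterf6-1. Per the labels' protocols, plants were grown on soil in a greenhouse at about 120 µmol photons per square metre and second with 16 h of light and 8 h of dark, leaves of equal age were frozen at the stage of 8 leaves, and biotinylated cRNA was made from 5 µg of total RNA. The arrays are named here by genotype and by the biological replicate number of the labels.

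The deposited values are log2 summaries of each probe set, 1 column per array, made by the authors with RMA per the submitters' processing notes. The RMA version, the probe set definition and any genome build are not given in the sources used here. That the scale is log2 was read from the values. The deposited table had 22810 rows, of which 64 were control probe sets, so that 22746 were tested. No other column of values was in the table. The medians of the arrays lay between 6.38 and 6.55, and no array was a copy of another, since correlations between arrays lay between 0.952 and 0.992. Scanner intensities were not used here, so neither the signal over background nor another background correction was examined. The number of arrays limits the precision.

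Probe sets were named from GEO's platform annotation, and names were updated through the TAIR10.1 gene table, which was used only for names and for the order of genes. The annotation gave 1 gene for 13513 probe sets, several for 503 and none for 8730, and 13436 of those with 1 gene were found in the gene table. Probe sets with several genes or none were tested and stay unnamed. No probe set was listed for MTERF6 (AT4G38160), the gene that the mutant's second name refers to. The level of the mutated gene was therefore not analysed by name, and whether an unnamed probe set measures it was not tested.

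The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over 22746 probe sets), and a probe set was called at an adjusted p under 0.05. A second count took the called probe sets that changed at least 2-fold. On data simulated for this comparison over 22746 probe sets, 200 of those with a mean above the median were changed. Of those changed by 1 on the log2 scale 34.0% were recovered with 0 false calls. The share was 82.5% for a change of 2, with 10 false calls, and 91.5% for a change of 3, with 9 false calls. These shares do not cover dim probe sets. Noise was drawn independently for each probe set and array, so replicates that vary together were not simulated.

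Gene lists were compared with all other probe sets by camera with a preset correlation of 0.01, over lists with at least 5 measured members, and camera with an estimated correlation and fry were run beside it. The 30 lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. The lists of nuclear genes were written as 433 loci, of which 64 had a probe set with 1 gene, so that 8 of the 30 lists could be tested. After the names of the probe sets had been seen, and before the genotypes were compared, 17 further lists were added, which were adjusted as a family of their own and are described among the additional observations. A gene in a list was represented by its probe set of highest mean. Plastid genes were recognised by their chromosome in the gene table and mitochondrial genes by their symbols. On simulated data with the plastid gene expression list raised, camera called that list and 1 other of the 8 tested, a list that contains its genes. The noise was again independent between probe sets, so camera was not tried on lists whose members vary together. In the data the estimated correlation of the raised list was 0.53.

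The genes to be named were the 5 largest rises and the 5 largest falls among called probe sets with 1 gene and no overlap between the genotypes, and in each list the 2 called members with the largest change, or where none was called the member with the largest change. This named 56 genes, of which 16 were called.

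The labels number the replicates of both genotypes alike. Deviations from the genotype means correlated between arrays of the same number with 0.53 for number 1, 0.20 for number 2 and 0.54 for number 3. As each was above the limit set beforehand, the numbers were taken to pair the arrays, on the evidence of the data and not of a statement in the labels. A fit with the replicate number as a block was run beside the fit without it, which had been chosen as the main one. The other alternatives were quantile normalization, median centring of each array, leaving out the 40% of probe sets with the lowest mean, eBayes with trend and robust settings, array weights, leaving out each array in turn, a threshold of 0.01 and lists that also take probe sets of several genes. The fit without pam48 replicate 1 was given a reading of its own after the data had been seen, since that array correlated least with the rest. Of the list medians, 5 of 150 moved by more than the spread between replicates when an array was left out, and 7 of 159 under the other settings.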

Results

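Leaf RNA of wild-type Arabidopsis and of pam48 was compared on 3 arrays each. The mutant's second name places it among mutants of the mTERF family, proteins of plastids and mitochondria related to mitochondrial transcription termination factors, and the comparison asks which transcripts differ in its leaves at the stage of 8 leaves. Changes are differences of mean log2 values, pam48 minus wild type, with their standard errors and n = 3 per genotype.

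Most of the called transcripts were higher in pam48. AT4G38150 rose the most, from 6.94 ± 0.26 to 13.45 ± 0.25 (SD, n = 3), which is 91.6-fold. Of 69 plastid-encoded transcripts 8 rose, 61 were not called and 0 were called lower, with ycf3, which encodes an assembly factor of photosystem I, 4.11-fold higher. AT2G21640, a gene of the response to mitochondrial dysfunction, rose 4.49-fold, and AT1G77960 was 4.81-fold lower in the mutant. Each of them was called in only 1 of the 6 fits that left out an array. The 6 nuclear photosystem genes measured had lower means in pam48, but none of them was called.

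In all, limma called 177 of 22746 probe sets, 136 of them higher and 41 lower in pam48, and 124 of them changed at least 2-fold, 95 up and 29 down. Of the called probe sets, 91 had 1 gene (73 higher and 18 lower), 8 had several and 78 were unnamed. At an unadjusted p under 0.05 were 3063 of the 22746, a share to set beside such counts in the lists. The genotypes did not overlap in 4670 probe sets, 20.5% of all, where chance gives 10% on average. Probe sets vary together, and this count was not made for other divisions of the arrays, so it is no test of the genotypes. With the replicate number as a block, 412 probe sets were called, 239 higher and 173 lower, and 164 of the 177 were among them. The count rested on single arrays: it was 1 without wild type replicate 1, 1 without wild type replicate 2, 1 without wild type replicate 3, 291 without pam48 replicate 1, 12 without pam48 replicate 2 and 39 without pam48 replicate 3.

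**Figure D1:**
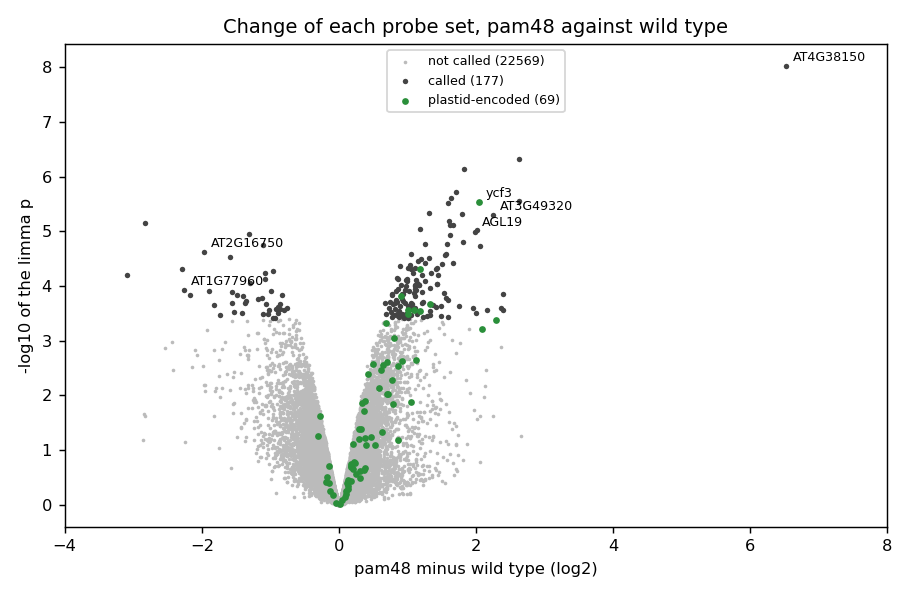
Each point is a probe set, with its change in pam48 against wild type (log2) on the horizontal axis and −log10 of its limma p on the vertical axis; dark points are the 177 called probe sets and green points the 69 plastid-encoded genes, called or not. AT4G38150 stands alone at 6.52, and plastid-encoded genes lie mostly to the right of 0.

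The rise of AT4G38150 was 6.52 ± 0.18 (SE, limma adjusted p = 0.000216), and it was called in each of the 6 fits that left out an array. The next largest rises of named genes were those of AT1G09500 by 2.39 ± 0.30 (limma adjusted p = 0.0361), AT3G49320 by 2.25 ± 0.17 (limma adjusted p = 0.0105), AT2G21640 by 2.17 ± 0.31 (limma adjusted p = 0.0439) and AT3G05170 by 2.06 ± 0.19 (limma adjusted p = 0.0171). The largest falls of named genes were those of AT1G77960, which fell by 2.27 ± 0.28, AT2G16750, which fell by 1.97 ± 0.19, AT3G26960, which fell by 1.90 ± 0.24, AT1G64360, which fell by 1.83 ± 0.25, and AT1G33340, which fell by 1.48 ± 0.19, with limma adjusted p between 0.0210 and 0.0414. Of the 6 fits that left out an array, AT3G49320 was called in 3, AT1G09500 and AT3G05170 in 2 each, and AT2G21640 in 1. Of the falls, AT2G16750, AT3G26960 and AT1G64360 were called in 2 each, and AT1G77960 and AT1G33340 in 1 each. Among called probe sets with no listed gene, the largest rise was 2.63 ± 0.14. The probe set with the largest fall fell by 3.10 ± 0.35, from 9.68 ± 0.11 to 6.58 ± 0.73 (SD, n = 3). In the array's numbering of probe sets it comes directly after that of AT4G38150, the neighbour of AT4G38160. Around these genes the numbering follows the gene order only in part, and whether this probe set measures AT4G38160 was not tested.

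AT4G38150 adjoins AT4G38160 in the gene table. Of 15 other measured genes within 20 loci on each side of AT4G38160, AT4G38010 rose by 1.33 ± 0.20 and AT4G38020 by 0.86 ± 0.11, and the other 13 were not called, with differences between −0.39 and 0.19; the risers were named after their values were seen.

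**Figure D2:**
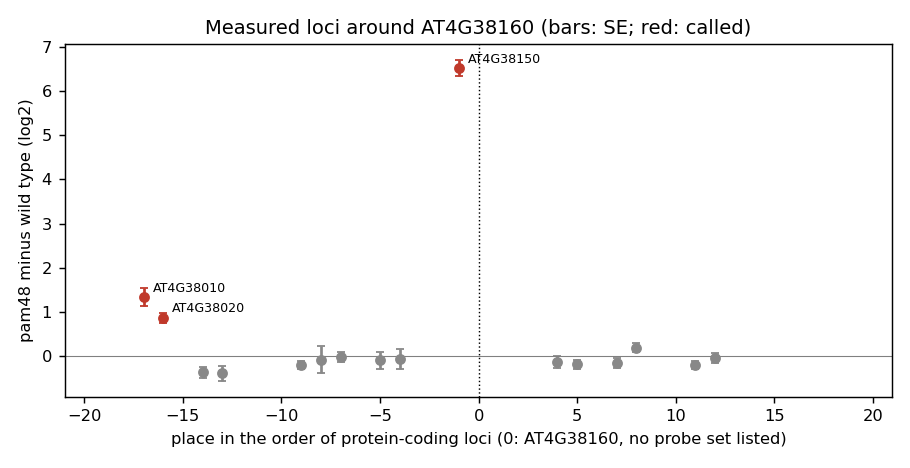
Change in pam48 against wild type (log2, bars SE) of the measured genes within 20 protein-coding loci on each side of AT4G38160, in their order on the chromosome, with called genes in red. AT4G38150 lies at 6.52, and of the 15 other genes AT4G38010 (1.33) and AT4G38020 (0.86) were called.

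Of the 69 plastid-encoded genes measured, 8 rose and 61 were not called, with a median change of 0.37; adjusted over the list alone, 29 rose. At an unadjusted p under 0.05, 32 were higher and 1 was lower. Besides ycf3 (2.04 ± 0.14, limma adjusted p = 0.00870), which was called in 3 of the 6 fits that left out an array, the called genes were accD, rps4, rps16, rpl14, rpl16, psaC and ndhD. By locus number ycf3 and rps4, rpl14 and rpl16, and psaC and ndhD are neighbours, so these calls may not be independent. The largest difference of the list, 2.29, was that of a gene not called. Camera put the list above all other probe sets (adjusted p = 7.5e-19), but not with an estimated correlation (adjusted p = 0.49). Without pam48 replicate 2 the median was 0.24 and 1 gene was called, without pam48 replicate 3 it was 1 gene, without any 1 wild-type array 0, and without pam48 replicate 1 it was 12.

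The list of plastid genes for gene expression held 22 genes, mostly of ribosomal proteins and of the plastid RNA polymerase, and all 22 had positive differences, with a median of 0.71. Of them 5 rose, and 16 rose when adjusted over the list alone; with the block 8 rose. The largest called changes were those of rps16, a protein of the small ribosomal subunit (1.33 ± 0.18, limma adjusted p = 0.0410), and rpl14, a protein of the large subunit (1.18 ± 0.17, limma adjusted p = 0.0450). A further called member, accD, encodes a subunit of acetyl-CoA carboxylase, an enzyme of fatty acid synthesis, and rose by 0.90 ± 0.12. The largest difference among the 22 genes, 2.29, was that of a member not called. The list passed camera (adjusted p = 7.5e-19), but not with an estimated correlation (adjusted p = 0.36); fry gave an adjusted p of 0.0372, and 0.161 with the block. No member was called when any array other than pam48 replicate 1 was left out, and 8 were called without that one; the list median lay between 0.56 and 0.79 in these fits. It was 0.56 without pam48 replicate 2, the array with the widest 3′ over 5′ difference of the actin control (2.75 on the log2 scale, against 1.60 to 2.01 on the others).

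Among 43 plastid genes for photosynthesis the median change was 0.22, and 2 rose, psaC by 1.09 ± 0.16 and ndhD by 1.01 ± 0.15, while 41 were not called; adjusted over the list alone, 7 rose. These called genes, psaC and ndhD, are neighbours by locus number. With the block 1 rose, as psaC was then not called (limma adjusted p = 0.0508). Without pam48 replicate 2 the median was 0.10; that array had a list mean 0.57 above wild type, against 0.11 and 0.19 on the other pam48 arrays. No member was called when any array other than pam48 replicate 1 was left out, and 3 were called without that one. The list passed camera (adjusted p = 2.2e-07), but not with an estimated correlation (adjusted p = 0.51). The mean of the gene expression list minus that of the photosynthesis list was −0.29 ± 0.05 in wild type and 0.24 ± 0.03 in pam48 (SD, n = 3), with no overlap between the genotypes (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays allow). None of 16 mitochondrion-encoded genes was called by limma, 2 had an unadjusted p under 0.05, the largest change was that of cox1 (0.52 ± 0.17), and camera did not call the list (adjusted p = 0.11), though it did without wild type replicate 3 (adjusted p = 0.0360) and without pam48 replicate 3 (0.0149).

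**Figure D3:**
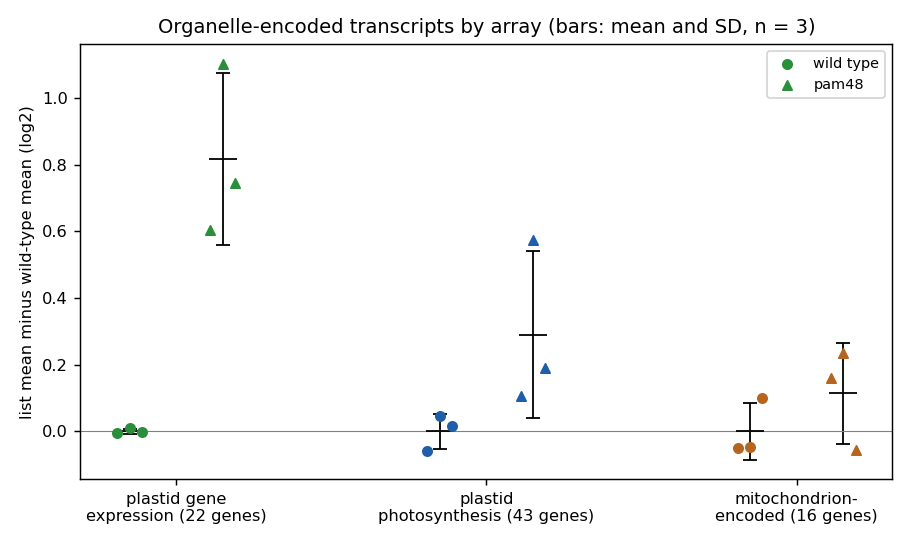
For each of 3 lists of organelle genes, points give each array's list mean minus the wild-type mean (log2), circles for wild type and triangles for pam48, with the group mean and SD (n = 3). The pam48 arrays lie at 0.60 or above for the plastid gene expression list and between 0.11 and 0.57 for the plastid photosynthesis list.

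Nuclear photosystem and electron transport subunits had negative differences in 6 of 6 members, with a median of −0.24. No member was called by limma, 3 had an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. The largest difference was that of PSBY, a small subunit of photosystem II, at −0.59 ± 0.15 (limma adjusted p = 0.16). Camera placed the list below other probe sets (adjusted p = 0.00541), but not with an estimated correlation (adjusted p = 0.49), and not without pam48 replicate 1 (adjusted p = 0.0559). The 3 light-harvesting antenna genes measured also had negative differences, the largest in LHCB4.3 (−0.85 ± 0.28), with none called, 2 at an unadjusted p under 0.05 and 2 lower when adjusted over the list alone.

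Carbon fixation and pigment genes were not called. In the Calvin-Benson cycle 1 of 3 genes had an unadjusted p under 0.05, SBPASE, which encodes sedoheptulose-bisphosphatase (−0.45 ± 0.13), and it was lower when adjusted over the list alone. In photorespiration 1 of 4 did, AT1G32470 (−0.45 ± 0.12), likewise. Tetrapyrrole synthesis had 2 of 9 at an unadjusted p under 0.05, with PORB, a protochlorophyllide oxidoreductase, at −0.77 ± 0.24, 0 when adjusted over the list alone and no call by camera (adjusted p = 0.11), except a lower one without pam48 replicate 3 (adjusted p = 0.00984). Of 9 nuclear genes for plastid ribosomal proteins 0 had an unadjusted p under 0.05, the largest difference was 0.19 ± 0.16 in AT4G17560, and the list was not called by camera (adjusted p = 0.22), except as higher without pam48 replicate 2 (adjusted p = 0.0343).

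Stress and defence lists were thinly measured. Of 4 genes of the mitochondrial dysfunction response AT2G21640 rose, and it was also the 1 gene called over the list alone. Limma called none in the lists that follow. STZ, a zinc finger gene and the 1 oxidative stress reporter measured, had a difference of 1.70 ± 1.25. Of 3 genes of salicylic acid defence 2 had an unadjusted p under 0.05 and 1 was higher over the list alone, while GRX480 had the largest difference (1.19 ± 1.17). PDF1.2, a defensin gene and the 1 jasmonate gene, was at 1.14 ± 0.37 with an unadjusted p of 0.0197, so that it was higher over the list alone. Of 5 flavonoid genes 0 had an unadjusted p under 0.05, with DFR, dihydroflavonol reductase, at 0.92 ± 0.75 and no call by camera (adjusted p = 0.11), except as higher without pam48 replicate 3 (adjusted p = 0.00703). Of 4 genes of abscisic acid and cold response 0 did, with COR15A at 0.29 ± 0.42. STZ and GRX480 were highest on pam48 replicate 1, at 11.52 and 10.44, against at most 8.55 and 7.82 on the other arrays.

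Of the remaining lists, limma called no member. IVD (0.04 ± 0.14) stood for dark and sugar starvation, WRKY6 (0.19 ± 0.14) for leaf senescence, BCAT4 (−0.22 ± 0.37) for glucosinolate synthesis, GI (0.10 ± 0.26) for the circadian clock, AUR1 (−0.29 ± 0.26) for cell division, Cpn60beta2 (0.51 ± 0.30) for plastid chaperones, AT1G77750 (0.21 ± 0.12) for the ribosomal proteins found by symbol and AT5G55580 (0.36 ± 0.23) for the mTERF family. AT5G15700 of the plastid transcription machinery was at 0.40 ± 0.13. Markers of other tissues were CLV3 of the shoot apex (−0.31 ± 0.11), PYK10 of the root (1.23 ± 1.28) and FMA of guard cells (−0.41 ± 0.13). AT5G15700, CLV3 and FMA had an unadjusted p under 0.05, which for a list of 1 gene is also the call over the list alone, and the others did not. No member of the lists for retrograde signalling and for cytosolic heat shock was measured by a probe set with 1 listed gene.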

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

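The separate reading of the fit without pam48 replicate 1 and the tests of the further lists were chosen after the data or the names of the probe sets had been seen. The count of 177 called probe sets (136 higher, 41 lower, 124 at least 2-fold) became 412 (239, 173 and 255) with the replicate block and 351 (258, 93, 177) with array weights, and 8 probe sets had an adjusted p under 0.01. Leaving out 1 array gave 1 to 291 called probe sets, 1 to 238 higher, 0 to 53 lower and 1 to 186 at least 2-fold; the cause was not tested, and it is not the number of arrays alone, as fits of equal size made 1 and 291 calls. Quantile normalization, median centring, the filter on dim probe sets and the trend and robust settings gave 166 to 177 calls. The 4 lists past the threshold became 0 with an estimated correlation and 1 with fry, and 3 to 7 when an array was left out. The 5 further lists became 3 with median centring, 3 without dim probe sets, 0 with an estimated correlation, 1 with fry, and 3 to 6 when an array was left out. Of the 56 named genes no called one turned its direction. The others that did were COR15A (−0.12), IVD (−0.056) and GI (−0.14) with array weights and in IVD with median centring (−0.0098). When 1 array was left out, changes spanned 0 in DFR (−0.0085 to 1.54), GRX480 (−0.11 to 1.98), COR15A (−0.075 to 0.68), IVD (−0.066 to 0.15), BCAT4 (−0.52 to 0.18), GI (−0.12 to 0.37) and CML38 (−0.63 to 1.76). These fits did not use the block, so each also broke a pair of arrays. When an array was left out, 65 of 336 values of named genes lost their call and 1 gained one; under the other settings 2 of 329 lost it and 7 gained it. The block ended the call of psaC and added 5 of these. What signal over background limits was not examined.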

Other observations

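The tests of AT4G38150 on single arrays, of its whole segment, of RNA integrity, of organelle RNA and of touch genes were chosen after the results had been seen, and so were the 17 further lists after the names of the probe sets had been seen. In these lists limma called 1 gene, AGL19, a MADS-box gene that promotes flowering, which rose by 1.98 ± 0.17 (limma adjusted p = 0.0129) in a list of 40 AGAMOUS-like genes that camera did not call (adjusted p = 0.47). Camera placed 14 organelle RNA editing and PPR proteins above other probe sets (median 0.50, adjusted p = 3.3e-05, but adjusted p = 0.28 with an estimated correlation). Of them 0 were called by limma (2 with the block) and 7 had an unadjusted p under 0.05, with the largest difference in OTP81 (1.08 ± 0.18). The counts hold for the 14 genes written into the list. Other such genes may be among the called ones, as 11885 probe sets with 1 gene were named by locus only. Camera placed 4 lists below other probe sets: 27 expansins and xyloglucan transferases, enzymes and proteins that loosen the cell wall (median −0.23, adjusted p = 0.000419), 9 tubulins and actins (−0.37, adjusted p = 0.00731), 17 sugar transporters (−0.16, adjusted p = 0.0435) and 22 trichome birefringence-like genes (−0.18, adjusted p = 0.0435). With an estimated correlation their adjusted p lay between 0.28 and 0.33, and with the block the sugar transporters were not called (adjusted p = 0.0739). The expansin median was −0.43 without wild type replicate 2 and −0.75 without the dimmest 40 percent of probe sets, and the list stayed called in both fits (adjusted p = 2.8e-05 and 0.00114). The sugar transporters also lost the call without wild type replicate 1, wild type replicate 2 or pam48 replicate 2 (adjusted p = 0.0953, 0.0722 and 0.184). The trichome birefringence-like genes lost it without any 1 array other than pam48 replicate 1 (adjusted p = 0.0588 to 0.0752), and the sugar transporters lost it with quantile normalization (0.0608); both lists lost it with median centring (0.0724 and 0.0712) and without the dimmest 40 percent of probe sets (0.131 and 0.176). Limma called none of their members, while 6, 2, 2 and 2 of them had an unadjusted p under 0.05. Of all 22746 probe sets 3063 did. EXPB1 was at −2.42 ± 0.54, TUB1 at −0.76 ± 0.37, SWEET13 at −1.25 ± 0.37 and TBL45 at −0.87 ± 0.32; with the block EXPB1 (limma adjusted p = 0.0266) and SWEET13 (0.0359) were called.

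The other 11 of these lists were not called by camera, with adjusted p of 0.16 or more, and limma called none of their members. The 96 cytosolic ribosomal protein loci were placed higher without pam48 replicate 1 (adjusted p = 1.9e-05) and with array weights (0.000624), but lower without pam48 replicate 3 (0.0418). These calls used the preset correlation. On all arrays this list had an estimated correlation of 0.65, and an adjusted p of 0.96 by camera with it. Photosystem assembly factors were placed lower without pam48 replicate 3 (adjusted p = 0.0174), and glutathione transferases with array weights (0.0373). The largest differences were those of NdhS among photosystem assembly factors (−0.63 ± 0.21), GSTF4 among glutathione transferases (−1.09 ± 0.19), UGT76C2 among glycosyltransferases (−1.63 ± 0.38), ATG8D in autophagy (0.42 ± 0.29), D2HGDH in branched-chain amino acid breakdown (0.28 ± 0.12), ACLA-1 in the tricarboxylic acid cycle (−0.40 ± 0.13), CML38 among calmodulin-like genes (0.91 ± 1.24), BZIP60 in endoplasmic reticulum stress (0.60 ± 0.21), COR27 among cold genes (1.68 ± 1.43), AT3G57490 among 96 cytosolic ribosomal protein loci (−0.69 ± 0.13) and AT2G34620 among 17 mTERF loci (−1.54 ± 0.37). With the block GSTF4, UGT76C2 and AT2G34620 were called as lower (limma adjusted p = 0.0484, 0.0266 and 0.0290), and among the mTERF loci AT1G78930, named after its value was seen, as higher (limma adjusted p = 0.0417). Medians and means of the glycosyltransferase, autophagy, calmodulin-like, ribosomal and mTERF lists differ in sign, and camera placed the cold list on the lower side although its median and mean are above 0.

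The 6 arrays can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real division called 177 probe sets and 124 at least 2-fold, 1 of the 10 reaching as many in each case, and the highest other count was 0 in both, also among the 3 others that part all pairs. For the gene lists 5 of the 10 divisions put as many past the threshold as the real one, which had 4, and the highest had 8.

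The list of plastid genes for gene expression lay above other probe sets in pam48 by camera with the preset correlation, but not with an estimated one (adjusted p = 0.36); fry, which tests the list against no change, gave an adjusted p of 0.0372, and 0.161 with the block. Uneven RNA integrity, as far as the actin control shows it, is argued against as the whole cause by a list median of 0.56 without pam48 replicate 2. This lay above the bound of 0.35 set for it by more than the SD of the remaining pam48 arrays, 0.10. The actin control does not measure the integrity of plastid RNA, which was not tested. A general gain of organelle RNA in the labelled samples as the whole cause is argued against by the list mean minus that of the photosynthesis list, which changed by 0.53 with an SD of 0.05 in wild type and 0.03 in pam48 (exact permutation p = 0.1, the smallest possible), and compression of bright probe sets as the cause of that difference by a gap of 0.45 between the list medians at matched level, against 0.49 without matching. Such a gain as part of the cause, up to the rise of the photosynthesis list mean, 0.29 on all arrays and 0.15 without pam48 replicate 2, remains open: the gene expression list mean rose by 0.70 more than that of mitochondrial genes, but 3 of those 16 genes lie above the median probe set, too few to decide, and changed by 0.20 to 0.52. Limma and fry compare the genotypes but not the causes of a difference. An effect of the mutation on plastid transcripts stays among the open explanations, and no value here tests it as the cause.

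AT4G38150 is the neighbour of AT4G38160 in the gene table. A single aberrant array as the cause is argued against by the lowest rise over the 6 fits that left out an array, 6.37. A rise of the whole segment alike is argued against by a median of −0.12 (SD 0.36) over the 10 neighbours above the median probe set, beside 6.52 for AT4G38150. A change that reaches parts of the segment unevenly remains open: of 15 other measured genes within 20 loci on each side, 2 were called, AT4G38010 (1.33 ± 0.20) and AT4G38020 (0.86 ± 0.11), and the other 13 lay between −0.39 and 0.19; the 2 fall between the bounds of 1 and 5 set beforehand, where 0.117 would be called at the share of all probe sets. A local effect of the mutation on AT4G38150 is a candidate explanation that no value here tests.

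The array of pam48 replicate 1 stood apart, with a mean correlation with the others of 0.964 against 0.978 to 0.984. Uneven RNA integrity is argued against by the actin control, whose 3′ over 5′ difference on that array ranked 4 of 6. Handling or wounding at harvest may have contributed: of 10 touch- and wound-induced genes, 6 had been listed with their changes seen, so the test rests on the 4 others, ORA47, PUB22, PUB23 and PUB24, whose mean on that array, 7.06, exceeded the next highest pam48 array by 1.43. Wild type replicate 1 was next of all 6 arrays, at 5.90, so that the arrays numbered 1 were the highest of both genotypes. Over all 10 the mean was 8.14 on that array and at most 5.94 on the others. The 4 genes were listed for the same responses as the 6 already seen, so they are no independent test. Other stresses induce the listed genes too, and the labels record none.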
